A study of Homo sapiens with 240 samples.

How the data were processed

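Polyadenylated RNA was measured in 240 libraries of HEK 293T cells, 3 per group in 80 groups. Per the labels, cells were grown in DMEM with 10% fetal bovine serum, and RNA was extracted with the RNeasy Plus kit. Per the submitters' processing notes, reads were checked with FastQC, aligned to GRCh38 with STAR and counted with HOMER, for which no versions are given. The deposited tables hold TPM (transcript abundance scaled by length and library) made by the authors, one table for each of the AMPK, FNIP1, TFEB and TFE3, ESRRA and PGC1A experiments. Each table keeps 1 transcript for each of 27234 genes, no mitochondrially encoded gene is among them, and symbols such as ATP5B and CTGF are those of the tables. TPM were normalized separately in each table and keep no read counts. Depth per library is therefore unknown, and the precision of each level can be judged only from the spread of 3 libraries. The TPM of the listed genes summed to between 396341 and 449208 per library, close between libraries but well under the full unit sum.

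Libraries were grouped by the genotype, treatment, time and replicate number of their titles and label tags. For 3 WT libraries titled as phenformin at 2 h the description gives 991, and for 3 WT libraries titled as CCCP at 4 h the description gives 16 h. These were placed by title and tags, and no library was left out of the planned tests. The design names phenformin and rotenone, which the titles shorten to Phen and Rot. Gene lists, the tests, the other settings and the rule for naming genes were set from the labels before the data were examined. Only the grouping, the TPM and the labels were used, and raw reads were not analysed here.

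Genes with TPM of at least 1 in at least 3 libraries of a table were kept, which left 13317 to 13746 genes per table. Values were taken as log2(TPM + 1), and a model with 1 mean per group was fitted to all libraries of a table with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level. Each treated time was compared with DMSO of the same arm, the altered arm with its control arm under DMSO, and the response of the altered arm with that of the control arm as a difference of differences. Genes changed over a whole time course were called with a moderated F statistic over all times. Adjustment was by Benjamini-Hochberg, with calls at an adjusted p under 0.05. Coordinates are 1-based on GRCh38, the build of the submitters' processing notes.

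Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over all lists and comparisons of a table, and again with the correlation estimated from the data. Of 33 lists, 32 had measured members, and the median log2 change of the members is given as the value of a list. Lists described are lysosomal proteins, the nuclear respiratory chain, the integrated stress response, ribosome biogenesis, autophagy, the folliculin complex, PGC-1 and its partners, the tricarboxylic acid cycle, cytosolic ribosomal proteins, G2/M genes, cholesterol synthesis, glycolysis, and markers of other cell types. Named genes were the target genes, a panel of 31 genes fixed beforehand, up to 5 rises and 5 falls per comparison, and up to 2 rises and 2 falls of each described list. Of these the text names a part, and genes that share reads with close copies, antisense genes and short RNAs were passed over because their values are uncertain.

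Other settings set beforehand were median-ratio scaling, quantile normalization, a pseudocount of 0.1, no filter on low values, the replicate number as a block, each replicate number left out of every group in turn, a fit of only the groups compared, and the estimated correlation. After the FNIP1 table had been seen, 2 more were added that leave out its outlying SA5 libraries. The test of time courses was run on simulated data built from the tables. In WT cells of the AMPK table, simulated changes of log2 0.5 were found in 98.5 percent of 67 genes with 19 false calls in 12866 genes, and in the FNIP1 table in 26.9 percent with 11 false calls in 13032 genes. Simulated list shifts of log2 0.4 were called in 10 of 10 shifted and 5 of 308 other lists. Smaller shifts and correlated genes were not simulated. Libraries were regrouped within comparisons, in all 10 splits of 3 against 3 or 100 draws for time courses. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.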

Results

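RNA levels were measured in 240 libraries of HEK 293T cells, a line derived from human embryonic kidney, arranged as 80 groups of 3 libraries in 5 tables. AMPK, the kinase that responds to low cellular energy, was tested in wild-type (WT) and knockout (KO) cells given DMSO, the AMPK activator 991, the uncoupler CCCP, or the complex I inhibitors phenformin (Phen) and rotenone (Rot) for 2, 4, 8 or 16 h. FNIP1, the partner of the lysosomal GTPase regulator FLCN, was tested in knockout cells carrying either WT FNIP1 or SA5, a form with 5 AMPK phosphosites changed to alanine. TFEB and TFE3, which switch on lysosomal genes, the nuclear receptor ESRRA and the mitochondrial coactivator PGC-1α (PPARGC1A) were tested by double knockout (DKO), knockout and siRNA, each with 991 for up to 24 h. DMSO was given only as a 0 h group, so every change over time also carries time in culture and handling. Levels of named genes are mean TPM ± SD of 3 libraries, and changes are differences in log2(TPM + 1) ± standard error, a scale that understates the change of genes near 1 TPM. For gene lists, counts over the list alone are of members whose p-values were adjusted within that list, and list p-values come from camera. The p-values measure only the spread between these libraries, because the labels do not state whether replicates are separate cultures.

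PRKAA1, which encodes the α1 catalytic subunit of AMPK (GRCh38, chromosome 5, 40759379 to 40798195), stood at 2.55 ± 0.338 against 6.94 ± 0.599 TPM in KO against WT cells under DMSO (-1.17 ± 0.08, adjusted p = 2.5e-22). Its KO and WT libraries did not overlap at any time or treatment (2.15 to 3.73 against 6.03 to 10.6 TPM, n = 51 per arm). PRKAA2, the α2 subunit gene (chromosome 1, 56645317 to 56715335), was also lower (4.36 ± 0.224 against 6.02 ± 0.346 TPM; -0.39 ± 0.07, adjusted p = 1.8e-06), but its arms overlapped (2.55 to 4.87 against 3.77 to 7.40 TPM). ESRRA (chromosome 11, 64306227 to 64316740) fell to 4.90 ± 0.685 against 8.17 ± 0.143 TPM in its knockout (-0.64 ± 0.10, adjusted p = 1.5e-05; arms 4.44 to 8.46 against 8.01 to 12.7 TPM). In the DKO, TFE3 (chromosome X, 49028726 to 49043517) was 7.75 ± 0.638 against 9.78 ± 0.542 TPM (-0.30 ± 0.06, adjusted p = 0.00026; arms 7.18 to 10.2 against 8.81 to 14.01 TPM). TFEB (chromosome 6, 41683978 to 41735527) did not differ in the libraries labelled DKO (1.71 ± 0.173 against 2.07 ± 0.237 TPM; -0.18 ± 0.14, adjusted p = 0.31; arms 1.32 to 2.72 against 1.24 to 3.56 TPM). PPARGC1A (chromosome 4, 23792021 to 23890077) was too low to be tested in the PGC1A table, and its siPGC1A libraries (0.0150 to 0.107 against 0.254 to 0.484 TPM) all lay below its siControl libraries. FNIP1 (chromosome 5, 131677597 to 131797063) did not pass between SA5 and WT cells (119 ± 98.2 against 233 ± 10.03 TPM; -1.99 ± 0.73, adjusted p = 0.063), with every SA5 library below every WT library (5.47 to 195 against 221 to 271 TPM). Its SA5 libraries under DMSO stood at 5.47, 179 and 172 TPM. With the first left out the difference was -0.40 (adjusted p = 0.64). With an outlying 8 h library left out as well it passed (adjusted p = 1.3e-05). Transcript levels need not report these edits, since a knockout can keep its RNA and SA5 alters only the protein, so the labels stand for the arms from here on.

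In WT cells of the AMPK table, FLCN (folliculin) rose at 4 h of 991 to 8.47 ± 0.240 against 5.81 ± 0.271 TPM (0.48 ± 0.06, adjusted p = 3.6e-09). Its partner gene FNIP2 rose too (0.52 ± 0.07, adjusted p = 1.5e-08). In the TFEB and TFE3 WT arm at 4 h FLCN did not pass (0.03 ± 0.08), but FNIP2 did (0.29 ± 0.07). RRAGD, a Rag GTPase gene, rose to 7.20 ± 0.460 against 4.77 ± 0.223 TPM in the AMPK table (0.51 ± 0.07, adjusted p = 1.3e-08). HEXA, a lysosomal hexosaminidase gene, rose at 4 h (0.42 ± 0.05, adjusted p = 2.4e-11) and more so at 16 h (41.8 ± 1.30 against 24.1 ± 1.65 TPM; 0.77 ± 0.05, adjusted p = 3.7e-23). HMGCS1, an early enzyme of sterol synthesis, rose at 4 h (0.64 ± 0.12, adjusted p = 1.0e-05). ID1, a target of BMP signalling, fell to 24.9 ± 3.61 against 65.6 ± 15.03 TPM (-1.34 ± 0.14, adjusted p = 1.6e-12). At 16 h NUPR1, a stress-induced chromatin factor gene, reached 11.2 ± 0.598 against 1.12 ± 0.304 TPM (2.54 ± 0.13, adjusted p = 5.2e-27), and the mTORC1 inhibitor gene DDIT4 91.5 ± 3.61 against 17.6 ± 1.38 TPM (2.31 ± 0.15, adjusted p = 1.7e-22). PCK2, a mitochondrial gluconeogenic enzyme gene, reached 26.5 ± 0.462 against 6.33 ± 0.485 TPM (1.91 ± 0.08, adjusted p = 4.2e-31). CTGF, a YAP target, was among the largest falls at 16 h (-2.60 ± 0.22, adjusted p = 4.2e-17). CYCS, which encodes the electron carrier cytochrome c, fell to 37.9 ± 1.07 against 54.3 ± 1.42 TPM (-0.51 ± 0.07, adjusted p = 2.7e-09).

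Over all times 11707 of 13617 genes changed with 991 in WT and 10841 in KO, 2493 and 1510 at least 1.5-fold. At 16 h 5709 rose and 3657 fell in WT, or 4650 and 4701 with median-ratio scaling, so the excess depends on it. Among lysosomal enzyme and membrane protein genes at 4 h, 28 of 73 rose, 11 fell and 34 did not pass, or 29 and 11 over the list alone. Their median change was 0.06 against 0.03 for all genes, and camera did not set the list apart (adjusted p = 0.33). At 16 h 42 of 73 rose, 11 fell and 20 did not pass, the same over the list alone, and the median of 0.17 did not pass (adjusted p = 0.056; 0.127, adjusted p = 0.0019, with no filter on low values). HGSNAT, which acetylates heparan sulfate in lysosomes, rose most (9.70 ± 0.186 against 4.07 ± 0.315 TPM; 1.08 ± 0.09, adjusted p = 9.0e-17). Nuclear genes of the respiratory chain and ATP synthase were lower at 16 h, when 12 of 75 rose, 30 fell and 33 did not pass, or 11 and 27 over the list alone. Their median was -0.07 against 0.07 for all genes (adjusted p = 0.0043, and adjusted p = 0.52 with an estimated correlation). Quantile normalization ended that call (-0.014, adjusted p = 0.87). Genes of the integrated stress response rose at 16 h, when 35 of 43 rose, 3 fell and 5 did not pass, the same over the list alone, with a median of 0.51 (adjusted p = 4.3e-10, and adjusted p = 0.16 with an estimated correlation). Ribosome biogenesis factors fell at 4 h, when 2 of 35 rose, 27 fell and 6 did not pass, the same over the list alone, with a median of -0.27 (adjusted p = 6.1e-15, and adjusted p = 0.093 with an estimated correlation). Among them was RRS1, which helps assemble the large subunit (27.9 ± 2.17 against 43.8 ± 2.50 TPM; -0.63 ± 0.05, adjusted p = 2.0e-17). FOSB, EGR3 and several histone genes also fell in this contrast, but their DMSO levels varied between libraries (FOSB 13.7 ± 10.99 TPM), so their changes remain uncertain.

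In AMPK KO cells FLCN did not pass at 4 h of 991 (7.72 ± 0.582 against 7.61 ± 0.868 TPM; 0.02 ± 0.06, adjusted p = 0.83), and its response was lower than in WT (-0.46 ± 0.09, adjusted p = 0.00031). The responses of FNIP1 (-0.43 ± 0.10, adjusted p = 0.0019) and FNIP2 (-0.40 ± 0.10, adjusted p = 0.0061) were also lower in KO cells at 4 h. RRAGD did not differ at 4 h (-0.15 ± 0.10, adjusted p = 0.36) and was lower at 16 h (-0.55 ± 0.10, adjusted p = 4.8e-05; 5.31 against 5.52 TPM in KO, 7.17 against 4.77 TPM in WT). The sterol genes HMGCS1 (-1.07 ± 0.17, adjusted p = 8.7e-06) and INSIG1, a sterol-regulated brake on that pathway (-1.54 ± 0.11, adjusted p = 5.5e-18), had lower responses in KO at 4 h. At 16 h INSIG1 stood below its DMSO level in KO and above it in WT cells (34.6 against 59.7 TPM in KO, 83.6 against 54.6 TPM in WT; -1.37 ± 0.11, adjusted p = 1.8e-15). CHAC1, a glutathione-degrading target of the stress response, responded more in KO cells at 4 h (11.3 against 2.51 TPM in KO, 2.94 against 3.11 TPM in WT; difference 1.84 ± 0.22, adjusted p = 1.1e-08). ASNS, which makes asparagine, reached 277 TPM in KO and 184 TPM in WT cells at 16 h (difference 0.62 ± 0.10, adjusted p = 4.4e-06). ESRRA, whose response to 991 in WT cells at 16 h was a rise (0.33 ± 0.07, adjusted p = 7.8e-05), did not pass for a difference (-0.28 ± 0.10, adjusted p = 0.053), nor did CYCS (-0.04 ± 0.10, adjusted p = 0.85). Without replicate 3 the 4 h differences lost their call for FLCN (adjusted p = 0.078), FNIP1 (adjusted p = 0.33), FNIP2 (adjusted p = 0.26) and HMGCS1 (adjusted p = 0.058). Without replicate 1 that of ESRRA passed (adjusted p = 0.039).

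The 991 response differed between KO and WT in 4376 genes over all times. That number ranged from 1044 to 5150 when each replicate number was left out of every group in turn and was 2029 when only the groups compared were fitted. Integrated stress response genes had the larger response in KO at 16 h, with 18 of 43 higher, 1 lower and 24 not passed, or 22 and 1 over the list alone. Their median difference was 0.25 against -0.04 for all genes (adjusted p = 3.5e-17, and adjusted p = 0.040 with an estimated correlation), and CTH, a cysteine synthesis gene, was among them (0.73 ± 0.10, adjusted p = 3.3e-08). Lysosomal genes did not differ at 4 h (0 of 73 higher, 3 lower and 70 not passed, or 0 and 2 over the list alone; median -0.05, adjusted p = 0.35). At 16 h the count was 0 of 73 higher, 15 lower and 58 not passed, or 1 and 17 over the list alone, with a median of -0.10 (adjusted p = 0.0027, and adjusted p = 0.28 with an estimated correlation). These included SLC38A9, an arginine sensor of the lysosomal membrane (-0.58 ± 0.11, adjusted p = 0.00014), and GLA, α-galactosidase (-0.58 ± 0.08, adjusted p = 6.9e-08). Autophagy genes were lower too (0 of 46 higher, 14 lower and 32 not passed, or 0 and 18 over the list alone), at a median of -0.12 (adjusted p = 0.00020, and adjusted p = 0.059 with an estimated correlation). WIPI1, which binds early autophagosomes, was the lowest (-0.79 ± 0.11, adjusted p = 3.4e-07). Respiratory chain genes had a slightly higher response in KO, with 6 of 75 higher, 1 lower and 68 not passed, the same over the list alone, at a median of 0.06 (adjusted p = 4.4e-05, and adjusted p = 0.31 with an estimated correlation; 0.026, adjusted p = 0.27, with quantile normalization). Ribosome biogenesis genes had a higher response in KO at 4 h (17 of 35 higher, 0 lower and 18 not passed, or 18 and 0 over the list alone; median 0.17, adjusted p = 2.8e-12, and adjusted p = 0.15 with an estimated correlation). FLCN, FNIP1, FNIP2 and RRAGD belong to the folliculin and Rag GTPase list, which as a whole did not pass at 4 h (2 of 30 higher, 4 lower and 24 not passed, the same over the list alone; median -0.06, adjusted p = 0.58).

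**Figure D1:**
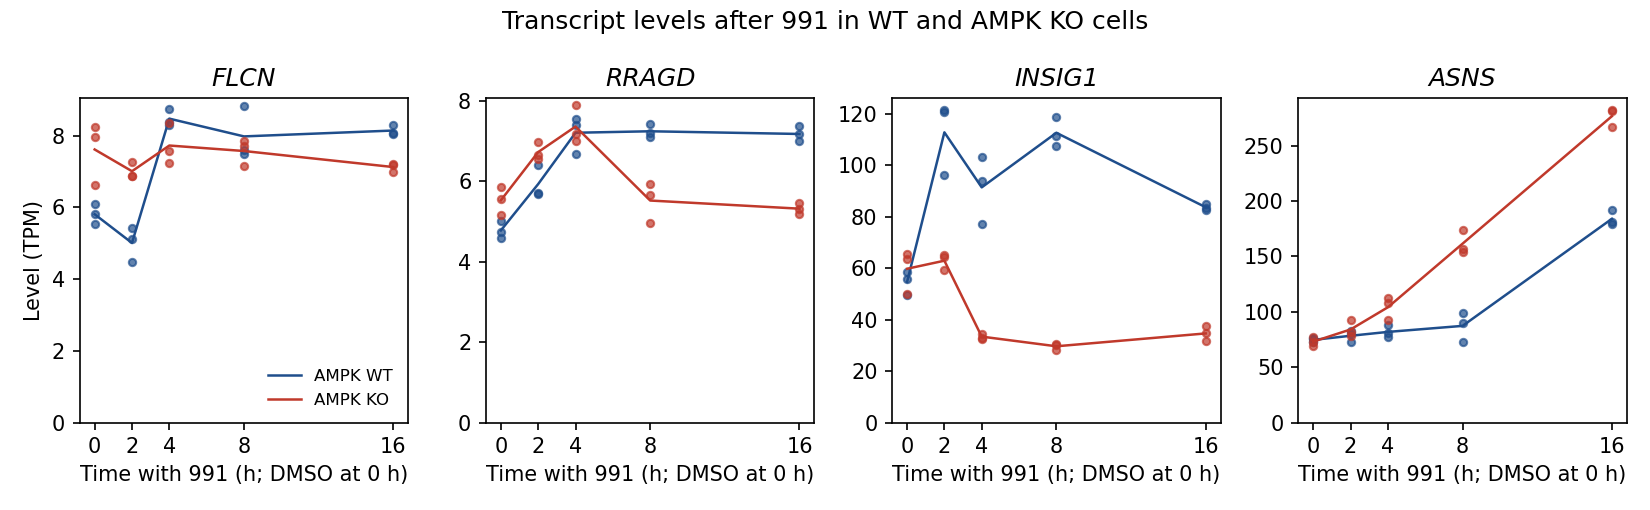
TPM of FLCN, RRAGD, INSIG1 and ASNS in WT and AMPK KO cells under DMSO (0 h) and 991, with 1 point per library and lines through the means of 3 libraries. The y axes start at 0, and DMSO was measured at 0 h only.

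Before treatment, KO cells lacked several transcripts of WT cells, such as CYBA, a subunit of NADPH oxidase (0.0730 ± 0.0910 TPM in KO, 23.4 ± 1.46 TPM in WT, -4.51 ± 0.06, adjusted p = 9.9e-65), and CDCA7L, a MYC partner (-4.42 ± 0.07, adjusted p = 8.8e-63). In all, 5299 genes differed, 2209 higher and 3090 lower in KO, or 2946 and 2618 with median-ratio scaling. The count was 3126 to 5710 with a replicate number left out and 3010 with only the groups compared. Ribosome biogenesis genes were higher in KO (26 of 35 higher, 4 lower and 5 not passed, the same over the list alone), at a median of 0.21 (adjusted p = 4.6e-09, and adjusted p = 0.26 with an estimated correlation). The medians of lysosomal (0.04, adjusted p = 0.14) and respiratory chain (-0.05, adjusted p = 0.25) genes did not pass, although quantile normalization set the respiratory chain apart (-0.057, adjusted p = 0.0029). Differences of this kind between 2 cell lines cannot be assigned to the lost kinase, because the number of clones is not stated.

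With phenformin at 16 h in WT cells, DDIT3, which encodes the proapoptotic factor CHOP, reached 148 ± 6.16 against 6.80 ± 0.247 TPM (4.25 ± 0.08, adjusted p = 5.4e-56). INHBE, an inhibin subunit gene induced by amino acid stress, reached 25.2 ± 1.32 against 0.111 ± 0.0479 TPM (4.56 ± 0.08, adjusted p = 7.3e-59). NUPR1 reached 24.6 ± 1.25 against 1.12 ± 0.304 TPM with CCCP (3.60 ± 0.13, adjusted p = 1.3e-36) and 40.1 ± 1.70 TPM with phenformin (4.28 ± 0.13, adjusted p = 2.5e-42). With rotenone it reached 7.97 ± 0.684 TPM (2.09 ± 0.13, adjusted p = 4.0e-22). SLC7A11, the cystine importer gene, was among the largest rises with rotenone (12.3 ± 0.464 against 2.69 ± 0.104 TPM; 1.85 ± 0.08, adjusted p = 5.7e-30). Phenformin lowered CYCS (-1.46 ± 0.07, adjusted p = 1.3e-30), the complex I gene NDUFB1 (-1.51 ± 0.06, adjusted p = 1.0e-34) and MRPL50 of the mitochondrial ribosome (-2.12 ± 0.06, adjusted p = 3.1e-43). The 3 mitochondrial poisons and 991 share the same DMSO libraries, so genes changed by several compounds are not independent findings.

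Integrated stress response genes rose with each compound at 16 h. With CCCP 40 of 43 rose, 1 fell and 2 did not pass, the same over the list alone, at a median of 1.05 (adjusted p = 1.4e-24). With phenformin 41 of 43 rose, 2 fell and 0 did not pass, the same over the list alone, at 1.32 (adjusted p = 1.0e-16). With rotenone 37 of 43 rose, 2 fell and 4 did not pass, or 38 and 2 over the list alone, at 0.62 (adjusted p = 6.2e-20). Lysosomal genes were not set apart at 4 h by any of the 3. Their median was -0.05 with CCCP (17 of 73 rose, 24 fell and 32 did not pass, or 16 and 22 over the list alone, adjusted p = 0.81) and -0.03 with phenformin (19 of 73 rose, 26 fell and 28 did not pass, the same over the list alone, adjusted p = 0.97). It was 0.02 with rotenone (17 of 73 rose, 20 fell and 36 did not pass, or 17 and 19 over the list alone, adjusted p = 0.93). Respiratory chain genes fell at 16 h with phenformin (4 of 75 rose, 61 fell and 10 did not pass, the same over the list alone), at a median of -0.34 against 0.07 for all genes (adjusted p = 4.0e-12, and adjusted p = 0.052 with an estimated correlation). With CCCP their median was -0.10 (12 of 75 rose, 38 fell and 25 did not pass, or 12 and 37 over the list alone; adjusted p = 8.9e-06, and adjusted p = 0.27 with an estimated correlation; -0.017, adjusted p = 0.47, with quantile normalization). With rotenone it was -0.03 (15 of 75 rose, 23 fell and 37 did not pass, or 14 and 21 over the list alone; adjusted p = 0.14; -0.076, adjusted p = 0.042, with median-ratio scaling). Markers of blood, endothelial, fibroblast and keratinised cells were mostly below the expression filter, and the 4 measured ones fell with rotenone at 16 h (4 of 4, median -0.67, adjusted p = 0.0040, and adjusted p = 0.15 with an estimated correlation).

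Between AMPK KO and WT cells the response to CCCP differed in 7081 genes, to phenformin in 2161 and to rotenone in 488 genes. FADS2, a fatty acid desaturase gene, had the higher CCCP response in KO (12.4 against 4.67 TPM in KO, 10.6 against 10.8 TPM in WT; 1.26 ± 0.12, adjusted p = 1.2e-13). DHRS3, a retinal reductase gene, had the lower (2.05 against 9.06 TPM in KO, 3.86 against 5.42 TPM in WT; -1.32 ± 0.12, adjusted p = 2.7e-14). With phenformin, GYPC, which encodes the membrane protein glycophorin C, responded less in KO (2.37 against 1.66 TPM in KO, 11.1 against 3.79 TPM in WT; -1.02 ± 0.20, adjusted p = 0.00016). With rotenone the glycine transporter gene SLC6A9 responded more (18.2 against 3.43 TPM in KO, 11.04 against 4.80 TPM in WT; 1.05 ± 0.17, adjusted p = 3.3e-05). The difference of lysosomal genes at 4 h of CCCP did not pass as a list (median -0.09; 2 of 73 higher, 24 lower and 47 not passed, or 3 and 24 over the list alone; adjusted p = 0.099). It passed with no filter on low values (-0.079, adjusted p = 0.0040). It did not pass with phenformin (-0.01; 0 of 73 higher, 3 lower and 70 not passed, or 0 and 4 over the list alone; adjusted p = 0.81) or rotenone (-0.02; 0 of 73 higher, 1 lower and 72 not passed, the same over the list alone; adjusted p = 0.35). At 16 h of CCCP they were lower in KO (4 of 73 higher, 28 lower and 41 not passed, or 5 and 29 over the list alone), at a median of -0.14 against -0.04 for all genes (adjusted p = 0.00027, and adjusted p = 0.17 with an estimated correlation). GLA was among the lowest (-0.83 ± 0.08, adjusted p = 1.3e-13). Respiratory chain genes had a higher response in KO with phenformin (22 of 75 higher, 1 lower and 52 not passed, or 30 and 1 over the list alone), at a median difference of 0.11 (adjusted p = 9.6e-15). ATP5G1 of ATP synthase was the highest (0.34 ± 0.06, adjusted p = 0.00013). With CCCP their difference did not pass (-0.03; 3 of 75 higher, 20 lower and 52 not passed, the same over the list alone; adjusted p = 0.50). It passed with quantile normalization (-0.062, adjusted p = 0.018). With rotenone their median was -0.03 (0 of 75 higher, 0 lower and 75 not passed, the same over the list alone, with limma giving 3 and 9 at unadjusted p < 0.05; adjusted p = 0.017, and adjusted p = 0.59 with an estimated correlation; -0.007, adjusted p = 0.47, without replicate 1). The calls of SLC6A9 (adjusted p = 0.056 without replicate 2) and ATP5G1 (adjusted p = 0.051 without replicate 3) also depend on 1 replicate number. Left-out replicates moved the counts to between 3652 and 7489 for CCCP, 318 and 3416 for phenformin, and 18 and 958 for rotenone.

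In cells carrying WT FNIP1, 991 raised RRAGD (0.70 ± 0.11, adjusted p = 7.0e-05 at 4 h; 8.13 ± 0.139 against 4.63 ± 0.416 TPM). FLCN (993 ± 11.8 against 973 ± 53.3 TPM) did not pass (0.03 ± 0.75, adjusted p = 0.99). Without outlying SA5 libraries it was 0.03 ± 0.05 (adjusted p = 0.63). The splicing factor gene SRSF6 fell to 35.5 ± 1.56 against 82.9 ± 0.857 TPM at 4 h (-1.20 ± 0.11, adjusted p = 8.7e-08). CHKA, which starts phosphatidylcholine synthesis, fell to 5.10 ± 0.134 against 13.2 ± 1.03 TPM (-1.21 ± 0.11, adjusted p = 4.1e-08). At 16 h NUPR1 rose to 16.5 ± 0.563 against 4.40 ± 0.954 TPM (1.71 ± 0.15, adjusted p = 4.9e-08). ACTA2, smooth muscle actin, rose to 15.6 ± 1.49 against 4.54 ± 0.713 TPM (1.59 ± 0.11, adjusted p = 1.5e-09). CD68, a lysosomal membrane glycoprotein gene, rose to 9.49 ± 0.947 against 3.49 ± 0.175 TPM (1.22 ± 0.13, adjusted p = 6.0e-07). Lysosomal genes rose at 4 h (16 of 74 rose, 0 fell and 58 did not pass, the same over the list alone), at a median of 0.18 against 0.10 for all genes (adjusted p = 0.042, and adjusted p = 0.99 with an estimated correlation). Median-ratio scaling ended that call (0.067, adjusted p = 0.34). At 16 h 20 of 74 rose, 0 fell and 54 did not pass, or 23 and 0 over the list alone, at a median of 0.23 (adjusted p = 0.0014, and adjusted p = 0.98 with an estimated correlation). Ribosome biogenesis genes fell at 16 h (0 of 35 rose, 19 fell and 16 did not pass, or 0 and 23 over the list alone; median -0.50, adjusted p = 1.8e-19). Respiratory chain genes did not pass (3 of 75 rose, 4 fell and 68 did not pass, or 2 and 4 over the list alone; median 0.01, adjusted p = 0.23). In all, 3002 of 13317 genes changed. This count depends on the spread estimated over the whole table, with 6405 without the first SA5 DMSO library, 9709 without the first SA5 8 h library too, and 644 to 7531 with a replicate number left out.

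SA5 cells differed from WT FNIP1 cells under DMSO in NTS, a neuropeptide gene (0.366 ± 0.160 against 33.02 ± 1.86 TPM; -4.64 ± 0.12, adjusted p = 7.3e-18) and TNMD, a tendon glycoprotein gene (-3.30 ± 0.11, adjusted p = 8.5e-16). MGST1, a microsomal glutathione transferase gene, was higher (5.30 ± 1.60 against 0.671 ± 0.186 TPM; 1.89 ± 0.17, adjusted p = 1.4e-07). The first SA5 DMSO library stood apart, with 9834 genes at 1 TPM or more against 12040 and 12036 in the others of its group, and FLCN at 26.9 TPM against 1017 and 1016 TPM. The first SA5 library at 8 h lay between the 2 states (FLCN 426 TPM). The DMSO library enters every SA5 contrast, and the all-gene median was -0.30 under DMSO, 0.23 for the difference at 4 h and 0.28 at 16 h. With limma, 0 genes had a different 991 response over all times (282 at unadjusted p < 0.05), 5 did with the first DMSO library left out and 37 with both left out. Simulated changes of log2 0.5, 1 and 2 in such differences were found in 10.4, 56.7 and 90.9 percent of genes, so small differences in this table remain open. CHAC1 responded more in SA5 at 16 h (12.7 against 3.69 TPM in SA5, 7.19 against 4.12 TPM in WT; 0.87 ± 0.13, adjusted p = 0.011), and still did with both libraries left out (0.85 ± 0.13, adjusted p = 0.0065). It did not with median-ratio scaling (0.543, adjusted p = 0.41) or quantile normalization (0.487, adjusted p = 0.48). RRAGD did not differ (0.06 ± 0.15, adjusted p = 0.79 at 4 h; with both left out -0.05 ± 0.13, adjusted p = 0.97).

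For lysosomal genes the SA5 minus WT difference at 4 h had a median of 0.18 below the 0.23 of all genes, and camera pointed down without passing (adjusted p = 0.45). The counts were 0 of 74 higher, 0 lower and 74 not passed, the same over the list alone, with limma giving 0 and 0 at unadjusted p < 0.05. With the first DMSO library left out the median was -0.03 (adjusted p = 0.14), so the positive median came from that library. Respiratory chain genes were lower at 16 h (median -0.24; 0 of 75 higher, 0 lower and 75 not passed, the same over the list alone, with limma giving 1 and 2 at unadjusted p < 0.05; adjusted p = 5.1e-17, and adjusted p = 0.16 with an estimated correlation). With the first DMSO library left out that median was -0.02 (adjusted p = 0.11). It passed at the same size with both left out (adjusted p = 0.021, and adjusted p = 0.35 with an estimated correlation). Genes of the integrated stress response were higher at 16 h at a median of 0.44 (1 of 42 higher, 0 lower and 41 not passed, or 15 and 0 over the list alone; adjusted p = 4.6e-07, and adjusted p = 0.58 with an estimated correlation). With both left out their median was 0.19 and 7 of 42 passed (adjusted p = 5.7e-22, and adjusted p = 2.2e-05 with an estimated correlation), SESN2, a nutrient-stress sensor gene, among them (0.44 ± 0.08, adjusted p = 0.012). The 1375 genes that differed under DMSO became 430 without the first DMSO library, 1815 without both and 2 with only the groups compared. NTS and TNMD kept their low level in all 3 SA5 libraries. Cytosolic ribosomal protein genes were higher in SA5 under DMSO (19 of 52 higher, 0 lower and 33 not passed, or 40 and 0 over the list alone; median 0.38, adjusted p = 5.4e-38, and adjusted p = 0.16 with an estimated correlation). Their median was 0.12 once the first library was left out (adjusted p = 1.6e-18, and adjusted p = 0.32 with an estimated correlation).

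In the WT cells of the TFEB and TFE3 table, 991 raised RRAGD to 8.05 ± 0.771 against 4.74 ± 0.326 TPM at 4 h (0.66 ± 0.06, adjusted p = 4.3e-10). TXNIP, an α-arrestin gene that restrains glucose uptake, rose to 24.97 ± 0.653 against 6.72 ± 0.618 TPM (1.75 ± 0.07, adjusted p = 5.6e-17). SHISA2, which retains Wnt and FGF receptors in the cell, was among the largest rises (15.97 ± 1.39 against 3.94 ± 0.542 TPM; 1.78 ± 0.11, adjusted p = 2.5e-13). SERTAD1, a cell cycle regulator, was among the largest falls (5.36 ± 0.245 against 25.1 ± 0.429 TPM; -2.04 ± 0.09, adjusted p = 3.1e-16). At 16 h the protease gene CTSD (83.2 ± 2.50 against 58.9 ± 3.58 TPM; 0.49 ± 0.05, adjusted p = 1.1e-09) and HEXA (46.98 ± 2.60 against 26.7 ± 1.34 TPM; 0.79 ± 0.05, adjusted p = 4.7e-14) had risen. DDIT3 stood at 38.97 ± 2.03 against 6.95 ± 1.08 TPM (2.34 ± 0.10, adjusted p = 1.5e-17). CYCS had fallen to 26.9 ± 2.51 against 52.5 ± 5.35 TPM (-0.94 ± 0.08, adjusted p = 3.3e-11). Lysosomal genes rose at 4 h (33 of 74 rose, 6 fell and 35 did not pass, or 35 and 7 over the list alone), at a median of 0.13 against 0.05 for all genes (adjusted p = 0.018, and adjusted p = 0.097 with an estimated correlation; 0.056, adjusted p = 0.069, with median-ratio scaling). At 16 h 53 of 74 rose, 5 fell and 16 did not pass, the same over the list alone, at 0.29 against 0.13 (adjusted p = 8.1e-05). Respiratory chain genes were lower at 16 h (6 of 75 rose, 30 fell and 39 did not pass, or 4 and 28 over the list alone; median -0.10, adjusted p = 5.5e-06, and adjusted p = 0.12 with an estimated correlation). This call was lost with quantile normalization (-0.005, adjusted p = 0.72). At 16 h genes of the integrated stress response (37 of 42 rose, 2 fell and 3 did not pass, the same over the list alone; median 0.50, adjusted p = 3.2e-15) rose. Ribosome biogenesis genes fell (1 of 35 rose, 32 fell and 2 did not pass, the same over the list alone; median -0.53, adjusted p = 5.6e-28). In all, 10718 of 13746 genes changed in WT cells, with 5651 higher and 2457 lower at 16 h, or 3863 and 4035 with median-ratio scaling.

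In DKO cells the response of HEXA (50.2 against 40.1 TPM in DKO, 46.98 against 26.7 TPM in WT; difference -0.47 ± 0.07, adjusted p = 2.4e-05) was smaller at 16 h, from a higher DMSO level. So was that of CTSD (98.4 against 92.5 TPM in DKO, 83.2 against 58.9 TPM in WT; -0.41 ± 0.07, adjusted p = 0.00020). NUPR1 (13.5 against 5.78 TPM in DKO, 29.4 against 3.52 TPM in WT; -1.66 ± 0.20, adjusted p = 1.7e-06) also responded less. DDIT3 did so as well (31.7 against 19.3 TPM in DKO, 38.97 against 6.95 TPM in WT; -1.65 ± 0.14, adjusted p = 3.0e-09). CYCS had the higher response (32.1 against 44.3 TPM in DKO, 26.9 against 52.5 TPM in WT; 0.49 ± 0.11, adjusted p = 0.0038). Without replicate 2 it did not pass (adjusted p = 0.13). The selective autophagy receptor gene NBR1 was lower in its response (-0.41 ± 0.06, adjusted p = 2.0e-05). RRAGD did not differ at 16 h (-0.15 ± 0.08, adjusted p = 0.27; 9.28 against 5.74 TPM in DKO, 8.70 against 4.74 TPM in WT), nor did FLCN (-0.25 ± 0.11, adjusted p = 0.13). The responses differed in 3690 genes over all times, with 747 to 1491 when a replicate number was left out. Lysosomal genes did not differ at 4 h (1 of 74 higher, 6 lower and 67 not passed, or 2 and 6 over the list alone; median -0.04, adjusted p = 0.34), although SLC29A3, a lysosomal nucleoside transporter gene, was lower (-0.62 ± 0.15, adjusted p = 0.017; adjusted p = 0.23 without replicate 3). At 16 h the count was 2 of 74 higher, 11 lower and 61 not passed, or 3 and 15 over the list alone, at a median of -0.10 against -0.01 for all genes (adjusted p = 0.0015, and adjusted p = 0.029 with an estimated correlation). In DKO cells the integrated stress response genes responded less at 16 h (0 of 42 higher, 25 lower and 17 not passed, or 0 and 27 over the list alone; median -0.21, adjusted p = 6.9e-17). Respiratory chain genes did not differ (5 of 75 higher, 4 lower and 66 not passed, or 4 and 2 over the list alone; median -0.01, adjusted p = 0.96).

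Under DMSO, DKO cells held far more HSPA6, an inducible chaperone gene that shares sequence with HSPA7 (32.02 ± 1.87 against 0.346 ± 0.211 TPM; 4.63 ± 0.09, adjusted p = 6.1e-25). CD68 (1.56 ± 0.10, adjusted p = 5.7e-13) and SQSTM1, the gene of the autophagy receptor p62 (0.81 ± 0.04, adjusted p = 7.7e-16), were higher. GLA was lower (223 ± 8.02 against 580.1 ± 28.5 TPM; -1.37 ± 0.04, adjusted p = 3.2e-22). Respiratory chain genes were lower (0 of 75 higher, 57 lower and 18 not passed, or 0 and 58 over the list alone), at a median of -0.20 against 0.11 for all genes (adjusted p = 3.9e-21). Cytosolic ribosomal protein genes were lower as well (0 of 52 higher, 48 lower and 4 not passed, or 0 and 49 over the list alone; median -0.32, adjusted p = 3.6e-38). Lysosomal genes did not pass (45 of 74 higher, 8 lower and 21 not passed, or 46 and 10 over the list alone; median 0.19, adjusted p = 0.052; 0.166, adjusted p = 0.0026, with no filter on low values). In all, 7047 genes differed, 5163 higher and 1884 lower, or 3232 and 3412 with median-ratio scaling.

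**Figure D2:**
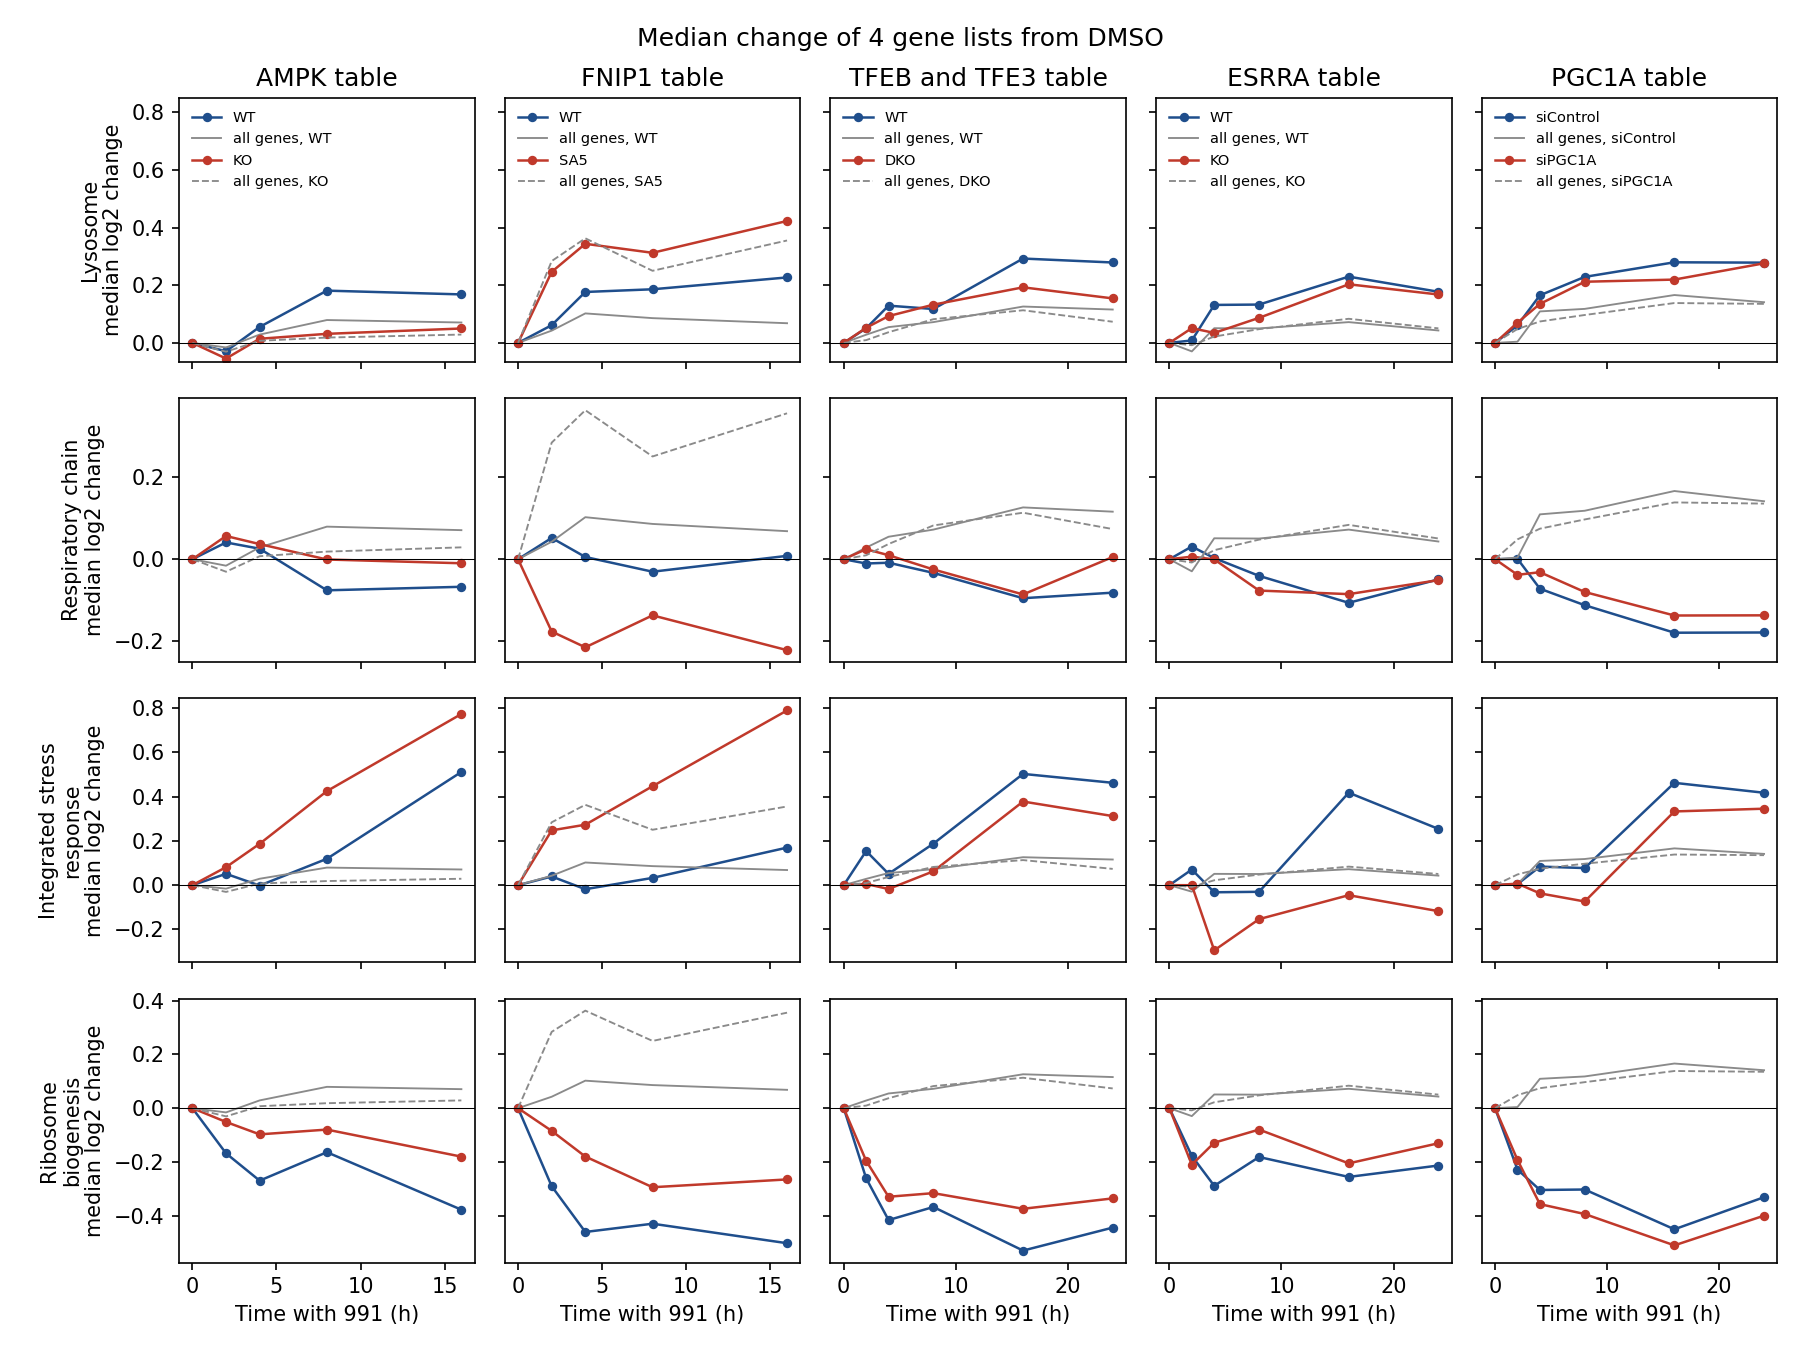
Median log2 change from DMSO of lysosomal, respiratory chain, integrated stress response and ribosome biogenesis genes after 991 in the 5 tables, for the control arm and the altered arm, with the median of all tested genes in grey. No error bars are drawn, and the SA5 arm carries the outlying first DMSO library.

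In the WT cells of the ESRRA table, 991 raised SLC16A9, a carnitine and monocarboxylate transporter gene, to 10.8 ± 0.822 against 2.57 ± 0.243 TPM at 4 h (1.73 ± 0.08, adjusted p = 4.9e-16). RRAGD rose to 10.04 ± 0.293 against 5.82 ± 0.0878 TPM (0.69 ± 0.07, adjusted p = 1.2e-08). The glutamate transporter gene SLC1A3 fell to 4.24 ± 0.424 against 10.95 ± 0.186 TPM (-1.19 ± 0.06, adjusted p = 1.9e-14). At 16 h RHOB, a GTPase of endosomes, stood at 167 ± 12.3 against 52.03 ± 2.14 TPM (1.66 ± 0.05, adjusted p = 2.4e-19). ASNS stood at 143 ± 7.76 against 77.5 ± 0.300 TPM (0.87 ± 0.07, adjusted p = 2.7e-11), and the splicing factor gene SRSF5 at 78.1 ± 1.05 against 185 ± 10.3 TPM (-1.23 ± 0.05, adjusted p = 7.3e-17). ESRRA itself rose to 11.7 ± 1.32 against 8.17 ± 0.143 TPM in WT cells (0.47 ± 0.10, adjusted p = 0.00020). The transcript left in KO cells changed alike (7.24 ± 1.14 against 4.90 ± 0.685 TPM; difference 0.01 ± 0.14, adjusted p = 0.98). Lysosomal genes rose at 4 h (29 of 73 rose, 3 fell and 41 did not pass, or 30 and 3 over the list alone), at a median of 0.13 against 0.05 for all genes (adjusted p = 0.0091, and adjusted p = 0.061 with an estimated correlation). At 16 h 45 of 73 rose, 3 fell and 25 did not pass, or 48 and 5 over the list alone, at 0.23 (adjusted p = 2.3e-05), and GAA, acid α-glucosidase, rose most (0.90 ± 0.06, adjusted p = 1.0e-11). Respiratory chain genes were lower at 16 h, when 6 of 75 rose, 31 fell and 38 did not pass, the same over the list alone, at a median of -0.11 (adjusted p = 6.2e-07). Under quantile normalization that call was lost (-0.050, adjusted p = 0.092). Integrated stress response genes rose (37 of 42 rose, 0 fell and 5 did not pass, the same over the list alone; median 0.42, adjusted p = 9.2e-14). Ribosome biogenesis genes fell (2 of 35 rose, 26 fell and 7 did not pass, or 2 and 27 over the list alone; median -0.26, adjusted p = 1.2e-16). Over all times 10195 of 13378 genes changed.

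ASNS, PCK2 and the cystine importer gene SLC7A11 responded less to 991 in ESRRA KO cells at 16 h, from higher DMSO levels. ASNS was 116 against 154 TPM in KO, 143 against 77.5 TPM in WT (difference -1.27 ± 0.09, adjusted p = 3.7e-10). PCK2 was 29.6 against 30.1 TPM in KO, 34.7 against 14.8 TPM in WT (-1.19 ± 0.10, adjusted p = 2.1e-08). SLC7A11 was 3.90 against 5.49 TPM in KO, 5.36 against 2.77 TPM in WT (-1.16 ± 0.13, adjusted p = 1.2e-06). FNIP1 responded more in KO (0.38 ± 0.06, adjusted p = 0.00021; adjusted p = 0.052 without replicate 1), and CYCS did not differ (-0.13 ± 0.07, adjusted p = 0.31). Integrated stress response genes as a list were lower in their response at 16 h (0 of 42 higher, 24 lower and 18 not passed, or 0 and 34 over the list alone), at a median of -0.42 against 0.01 for all genes (adjusted p = 3.3e-54). They were higher under DMSO (29 of 42 higher, 0 lower and 13 not passed, or 32 and 0 over the list alone; median 0.30, adjusted p = 3.0e-32). Lysosomal genes responded slightly less at 4 h (0 of 73 higher, 5 lower and 68 not passed, the same over the list alone; median -0.06, adjusted p = 0.047, and adjusted p = 0.14 with an estimated correlation; -0.029, adjusted p = 0.10, with median-ratio scaling). Respiratory chain genes did not differ at 16 h (1 of 75 higher, 0 lower and 74 not passed, the same over the list alone; median -0.02, adjusted p = 0.42). The 991 response differed in 921 genes, or 82 to 197 with a replicate number left out.

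Under DMSO, ESRRA KO cells had lower OGDH, a subunit of the 2-oxoglutarate dehydrogenase complex (-0.37 ± 0.04, adjusted p = 6.9e-08), and PDHA1 of pyruvate dehydrogenase (-0.40 ± 0.04, adjusted p = 5.6e-08), and higher ASNS (0.98 ± 0.07, adjusted p = 2.4e-11). Tricarboxylic acid cycle genes as a list were lower (2 of 27 higher, 15 lower and 10 not passed, or 3 and 18 over the list alone; median -0.16, adjusted p = 0.00022). Respiratory chain genes were lower too (2 of 75 higher, 33 lower and 40 not passed, or 2 and 34 over the list alone), at a median of -0.10 against -0.04 for all genes (adjusted p = 5.1e-05, and adjusted p = 0.10 with an estimated correlation). Cytosolic ribosomal protein genes were higher (41 of 52 higher, 0 lower and 11 not passed, or 44 and 0 over the list alone; median 0.19, adjusted p = 5.2e-41), and RPL3 of the large subunit was among them (0.39 ± 0.03, adjusted p = 1.7e-11). In all, 2870 genes differed, 898 higher and 1972 lower, or 1284 and 1310 with median-ratio scaling. The count was 1363 to 1849 with a replicate number left out and 1414 with only the groups compared.

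In siControl cells 991 raised SLC16A9 to 6.77 ± 1.74 against 1.85 ± 0.143 TPM (1.42 ± 0.13, adjusted p = 2.4e-09). RRAGD rose to 9.55 ± 0.566 against 5.27 ± 0.311 TPM at 4 h (0.75 ± 0.07, adjusted p = 2.3e-09). CD68 (7.84 ± 0.735 against 1.85 ± 0.382 TPM; 1.64 ± 0.13, adjusted p = 4.4e-11) had risen at 16 h. CHAC1 had risen too (10.9 ± 0.526 against 2.80 ± 0.273 TPM; 1.64 ± 0.10, adjusted p = 6.8e-14). ATP5B, the catalytic subunit gene of ATP synthase, fell to 563 ± 11.5 against 689 ± 18.6 TPM (-0.29 ± 0.02, adjusted p = 3.8e-11). Over all times 9572 of 13404 genes changed, and at 16 h 5974 rose and 1668 fell, or 3148 and 3313 with median-ratio scaling. Lysosomal genes rose at 4 h (35 of 73 rose, 3 fell and 35 did not pass, the same over the list alone), at a median of 0.17 against 0.11 for all genes (adjusted p = 0.014, and adjusted p = 0.16 with an estimated correlation). That call was lost with median-ratio scaling (0.041, adjusted p = 0.11). At 16 h 49 of 73 rose, 3 fell and 21 did not pass, the same over the list alone, at 0.28 against 0.17 (adjusted p = 0.00062). Respiratory chain genes fell at 16 h (6 of 75 rose, 50 fell and 19 did not pass, or 6 and 53 over the list alone; median -0.18, adjusted p = 1.7e-19), with a median of -0.089 under quantile normalization (adjusted p = 0.0027). Ribosome biogenesis genes fell too (0 of 35 rose, 31 fell and 4 did not pass, or 0 and 32 over the list alone; median -0.45, adjusted p = 1.7e-30).

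Few genes differed in their 991 response between siPGC1A and siControl cells. DDX21, an RNA helicase of the nucleolus, was lower in its response at 16 h (54.04 against 84.95 TPM in siPGC1A, 85.3 against 93.2 TPM in siControl; -0.52 ± 0.08, adjusted p = 0.0020). So was LAPTM4B, a lysosomal membrane protein gene (38.6 against 49.1 TPM in siPGC1A, 110.2 against 99.3 TPM in siControl; -0.48 ± 0.09, adjusted p = 0.0070). CHAC1 responded less from a higher DMSO level (10.3 against 4.86 TPM in siPGC1A, 10.9 against 2.80 TPM in siControl; -0.69 ± 0.14, adjusted p = 0.016). COA1, a respiratory chain assembly factor gene, responded slightly more (0.31 ± 0.07, adjusted p = 0.030). These calls were lost without replicate 3 (adjusted p = 0.14 for DDX21, adjusted p = 0.46 for LAPTM4B, adjusted p = 0.34 for CHAC1, adjusted p = 0.14 for COA1). In all, 75 genes differed over all times, 22 with median-ratio scaling and 0 to 8 with a replicate number left out. Lysosomal genes did not differ at 4 h (0 of 73 higher, 0 lower and 73 not passed, the same over the list alone, with limma giving 1 and 3 at unadjusted p < 0.05; median -0.02, adjusted p = 0.96). Respiratory chain genes had a slightly higher response at 16 h (0 of 75 higher, 0 lower and 75 not passed, or 3 and 0 over the list alone, with limma giving 7 and 3 at unadjusted p < 0.05), at a median of 0.05 (adjusted p = 1.6e-05). Without replicate 3 that call was lost (0.020, adjusted p = 0.55). The integrated stress response list had a lower one (0 of 42 higher, 3 lower and 39 not passed, or 0 and 17 over the list alone; median -0.14, adjusted p = 1.2e-09). PGC-1 coactivators, estrogen-related receptors and their reported targets did not differ (0 of 19 higher, 0 lower and 19 not passed, or 0 and 1 over the list alone, with limma giving 1 and 3 at unadjusted p < 0.05; median 0.00, adjusted p = 0.61).

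Under DMSO the siPGC1A cells had lower RYK, a Wnt coreceptor gene (7.02 ± 0.321 against 20.2 ± 0.970 TPM; -1.40 ± 0.06, adjusted p = 1.6e-16). HPRT1 of purine salvage (-1.32 ± 0.07, adjusted p = 3.6e-15) was lower too. The annexin gene ANXA1 was higher (12.97 ± 1.75 against 4.37 ± 0.542 TPM; 1.38 ± 0.14, adjusted p = 2.2e-08). The labels do not say how many siRNAs were used, so effects of the siRNA sequence cannot be separated from loss of PPARGC1A. Integrated stress response genes were higher (24 of 42 higher, 2 lower and 16 not passed, or 26 and 2 over the list alone; median 0.20, adjusted p = 6.9e-10), DDIT3 among them (0.83 ± 0.09, adjusted p = 2.1e-08). In all, 3247 genes differed, 1922 higher and 1325 lower, or 1644 and 1628 with median-ratio scaling. The count was 1789 to 2385 with a replicate number left out and 1910 with only the groups compared.

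Across the 5 control arms, each with its own libraries, the genes that moved alike with 991 at 16 h were led by NUPR1 (mean log2 change 2.02, range 1.51 to 2.76 over the arms), CHAC1 (1.59, 0.68 to 2.23) and DDIT3 (1.41, 0.58 to 2.34). TXNIP (1.29, 0.44 to 2.26) and RHOB (1.36, 0.52 to 2.04) rose in all 5 as well. SRSF5 (-1.34, -1.64 to -0.96) and SRSF6 (range -1.87 to -0.64), which encode splicing factors, fell in all 5. DUSP5, a nuclear ERK phosphatase gene (-1.23, -1.54 to -0.61), and RRS1 (-0.89, -1.38 to -0.63) fell as well. At 4 h SLC16A9 (1.36, 0.99 to 1.73) and SDSL, a serine dehydratase-like gene (1.27, 1.08 to 1.62), rose in all 5. In total 826 of 12862 genes passed in the same direction in all 5 arms at 4 h and 1076 at 16 h. If the arms were independent, 13.6 and 39.2 would be expected from the counts of each arm. A further 3 and 23 genes passed in all 5 with mixed signs. The FNIP1 arm called the fewest genes, and with both outlying SA5 libraries left out they were 1811 and 2571. With a replicate number left out they ranged from 225 to 1184 at 4 h and from 267 to 1776 at 16 h.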

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

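The tests of the length trend and of the label of the first SA5 DMSO library, and of a shift of the whole distribution behind the respiratory chain list, were chosen after seeing results. Each result named here differed between the altered and the control arm by a test of the difference itself. The response to 991 differed in 4376 genes in AMPK KO cells, 3690 in TFEB and TFE3 DKO cells, 921 in ESRRA KO cells and 75 in siPGC1A cells. AMPK KO and WT cells also differed in the responses to CCCP (7081 genes), phenformin (2161) and rotenone (488). FLCN at 4 h and INSIG1 at 4 and 16 h belong to the AMPK KO differences, HEXA and DDIT3 at 16 h to those of the DKO, and ASNS at 16 h to those of the ESRRA KO.

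Respiratory chain genes had a median difference at 16 h of 0.06 between the 991 responses of AMPK KO and WT cells (adjusted p = 4.36e-05), 0.11 with phenformin (adjusted p = 9.56e-15) and -0.03 with rotenone (adjusted p = 0.017). The same list differed by -0.24 between SA5 and WT FNIP1 cells (adjusted p = 5.08e-17) and by 0.05 between siPGC1A and siControl cells (adjusted p = 1.61e-05). Lysosomal genes differed by -0.06 at 4 h between ESRRA KO and WT cells (adjusted p = 0.0467). Of these list differences, those of phenformin and siPGC1A kept their call with an estimated correlation and the others lost it, but that of siPGC1A was lost without replicate 3 (0.020, adjusted p = 0.55).

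When libraries were regrouped, 1 of 100 splits, the real grouping, reached the real count in most time courses and response differences, so chance can be excluded there, with real counts given against the highest of the other splits. These were 11707 against 9705 for 991 in AMPK WT, 10841 against 8456 in AMPK KO, 12346 against 10367 and 12366 against 10601 for CCCP, 12554 against 11008 and 12544 against 10734 for phenformin, and 10802 against 6802 and 11077 against 8223 for rotenone. The differences between AMPK KO and WT gave 4376 against 3054 for 991, 7081 against 3667 for CCCP and 488 against 125 for rotenone. For phenformin 2 of 100 splits reached the real count (2161 against 2622), so chance is even less firmly excluded there. The higher count of another split points to a structure of the samples, and the real count was 3416, 366 and 318 without replicates 1, 2 and 3. With 991 the control and altered arms gave 10718 against 5596 and 9663 against 2387 for TFEB and TFE3, 10195 against 4392 and 10625 against 3737 for ESRRA, 9572 against 5078 and 9464 against 3145 for PGC1A, and 3002 against 734 for WT FNIP1. Their differences gave 3690 against 148, 921 against 17 and 75 against 3 for TFEB and TFE3, ESRRA and PGC1A, and genes alike in all 5 control arms 826 against 0 at 4 h and 1076 against 0 at 16 h. Chance cannot be excluded for the SA5 time course (4399 against 8993, reached by 20 of 100 splits), where the higher count of another split points to a structure too, with neither source tested. For the SA5 difference the real count is 0, which all 100 of 100 splits reach by construction (highest other 1), so regrouping says nothing there. For the DMSO comparisons 10 splits exist and the share cannot fall under 0.05, with 5299 against 3351 in the AMPK table, 1375 against 0 in FNIP1, 7047 against 0 in TFEB and TFE3, 2870 against 1 in ESRRA and 3247 against 4 in PGC1A.

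The first SA5 DMSO library correlated with the others of its group at 0.891, and most of the respiratory chain difference of SA5 cells rests on it (-0.24 with it, -0.02 without). A trend with transcript length held 27.6 percent of its deviation, and after its removal the correlation was 0.910 against 0.992 for the lowest library of the other groups, or 0.966 for the first SA5 8 h library, which that reference leaves out, and this argues against length as the whole difference. Of 13 genes at least 2-fold higher in the other SA5 libraries than in WT, 12 (92.3 percent) lay above the WT mean in this library, although its median gene differed from WT by -0.74, which argues against a WT library under a wrong label. What set this library apart stays open.

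The respiratory chain list was lower at 16 h of 991 in 4 of the 5 control arms. Against 10000 random lists matched on transcript length and expression, its median lay below the central 95 percent in 2 of these arms, siControl (-0.18, lower end -0.12) and ESRRA WT (-0.11, -0.08), and inside it in the AMPK (-0.07, -0.08) and TFEB and TFE3 (-0.10, -0.11) arms. With quantile normalization it was called in 1 of the 4, siControl (-0.089, adjusted p = 0.0027). A cause in the length and level of the genes is thus not ruled out in the AMPK and the TFEB and TFE3 arms, nor is a shift of whole libraries in these and the ESRRA arm. In siControl cells, where ATP5B fell, both tests argue against these causes, and a response of the respiratory chain genes themselves stays open.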

How the results depend on the processing

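The tests that leave out the outlying SA5 libraries were chosen after seeing results, and all other tests here were set before. Lists are given by their median change, and a direction that turned is that of the median or of the camera test. Of the planned counts and lists, those that kept their call and direction were 31 of 31 and 31 of 32 with a pseudocount of 0.1, 30 of 31 and 28 of 32 with no filter on low values, 29 of 31 and 20 of 32 with median-ratio scaling, 29 of 31 and 22 of 32 with quantile normalization. Named genes kept theirs in 129 of 129 with a pseudocount of 0.1, 129 of 129 with no filter on low values, 125 of 129 with median-ratio scaling, 126 of 129 with quantile normalization, and lists described besides in 53 of 53, 48 of 53, 52 of 53, 50 of 53 in the same order. With 1 replicate number left out, 19 of 31, 16 of 31, 17 of 31 counts, 27 of 32, 27 of 32, 28 of 32 planned lists and 122 of 129, 118 of 129, 116 of 129 named genes kept theirs for replicates 1, 2 and 3. Depth is unknown without read counts, so which genes it limits cannot be told, and the filter at 1 TPM stands in for it.

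With an estimated correlation 20 of 32 planned lists kept their call, and these medians, unchanged in size, lost theirs: the respiratory chain list in AMPK WT 991 16 h -0.067, AMPK KO minus WT 991 16 h 0.057, AMPK WT CCCP 16 h -0.101, AMPK WT Phen 16 h -0.343, AMPK KO minus WT Rot 16 h -0.032, FNIP1 SA5 minus WT 991 16 h -0.236 and TFEB and TFE3 WT 991 16 h -0.095, and the lysosomal list in FNIP1 WT 991 4 h 0.177, TFEB and TFE3 WT 991 4 h 0.129, ESRRA WT 991 4 h 0.132, ESRRA KO minus WT 991 4 h -0.058 and PGC1A siControl 991 4 h 0.165. That test takes the correlation between members from the data, not the preset 0.01.

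With median-ratio scaling the direction turned for the respiratory chain list in AMPK KO minus WT CCCP 16 h 0.014, FNIP1 WT 991 16 h -0.076 and TFEB and TFE3 DKO minus WT 991 16 h 0.001, the lysosomal list in AMPK WT Phen 4 h 0.005, AMPK KO minus WT Phen 4 h 0.002, FNIP1 SA5 minus WT 991 4 h -0.142 and PGC1A siPGC1A minus siControl 991 4 h 0.006, the glycolysis list in AMPK KO minus WT 991 16 h 0.042, CYCS in AMPK KO minus WT 991 16 h 0.004, RRAGD in FNIP1 SA5 minus WT 991 4 h -0.203, and FLCN in FNIP1 WT 991 4 h -0.093. The call was lost for the lysosomal list in FNIP1 WT 991 4 h 0.067, TFEB and TFE3 WT 991 4 h 0.056, ESRRA KO minus WT 991 4 h -0.029 and PGC1A siControl 991 4 h 0.041. It was gained for the respiratory chain list in AMPK WT Rot 16 h -0.076. Counts moved for FNIP1 DMSO difference 804 (from 1375) and PGC1A 991 response difference 22 (from 75). The cause was not tested.

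With quantile normalization the direction turned for the lysosomal list in AMPK WT Rot 4 h -0.012 and FNIP1 SA5 minus WT 991 4 h -0.068, the respiratory chain list in AMPK WT Rot 16 h 0.015 and FNIP1 WT 991 16 h 0.056, the cholesterol list in AMPK WT 991 16 h 0.177, RRAGD in FNIP1 SA5 minus WT 991 4 h -0.299, and ESRRA in ESRRA KO minus WT 991 16 h -0.015. The call was lost for the respiratory chain list in AMPK WT 991 16 h -0.014, AMPK KO minus WT 991 16 h 0.026, AMPK WT CCCP 16 h -0.017, TFEB and TFE3 WT 991 16 h -0.005 and ESRRA WT 991 16 h -0.050. It was gained for the respiratory chain list in AMPK KO minus WT CCCP 16 h -0.062. Counts moved for FNIP1 991 response difference 1 (from 0) and FNIP1 DMSO difference 890 (from 1375). The cause was not tested.

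Without a filter on low values the direction turned for the lysosomal list in AMPK WT CCCP 4 h -0.049, AMPK WT Phen 4 h -0.031 and AMPK WT Rot 4 h -0.004, the cholesterol list in AMPK WT 991 16 h 0.172, the glycolysis list in AMPK KO minus WT 991 16 h 0.005, and the PGC-1 list in PGC1A siPGC1A minus siControl 991 16 h -0.034, the call was gained for the lysosomal list in AMPK KO minus WT CCCP 4 h -0.079, and the count moved for FNIP1 991 response difference 4 (from 0). With a pseudocount of 0.1 the direction turned for the respiratory chain list in TFEB and TFE3 DKO minus WT 991 16 h -0.013. More genes are tested without the filter, and the cause was not tested otherwise.

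With the replicate number as a block, counts moved for AMPK Rot response difference 794 (from 488) and FNIP1 991 response difference 1 (from 0), and the block changed no other planned count or list call. Outside the planned results it brought 2 past the threshold, ESRRA in AMPK KO minus WT 991 16 h and the lysosomal list in TFEB and TFE3 DKO minus WT DMSO. Libraries correlated best with one of their own number in 70.6 percent (AMPK), 15 of 30 (FNIP1), 61.1 percent (TFEB and TFE3), 58.3 percent (ESRRA), 63.9 percent (PGC1A) of cases, and not every pair correlated above 0.1, so the numbers are not taken to pair the libraries.

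With only the groups compared in the fit, 21 of 29 counts kept their size, and others moved for AMPK 991 response difference 2029 (from 4376), AMPK Phen response difference 880 (from 2161), AMPK DMSO difference 3010 (from 5299), FNIP1 WT 991 time course 9464 (from 3002), FNIP1 SA5 991 time course 1400 (from 4399), FNIP1 DMSO difference 2 (from 1375), ESRRA DMSO difference 1414 (from 2870) and PGC1A DMSO difference 1910 (from 3247). Such a fit estimates the spread from fewer libraries.

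With the first SA5 DMSO library left out, counts moved for FNIP1 WT 991 time course 6405 (from 3002), FNIP1 991 response difference 5 (from 0), FNIP1 DMSO difference 430 (from 1375), all 5 control arms at 4 h 1459 (from 826) and all 5 control arms at 16 h 2002 (from 1076). The direction turned for the lysosomal list in FNIP1 SA5 minus WT 991 4 h -0.026, and RRAGD in FNIP1 SA5 minus WT 991 4 h -0.055. The call was lost for the respiratory chain list in FNIP1 SA5 minus WT 991 16 h -0.020.

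With the first SA5 DMSO and first SA5 8 h libraries left out, counts moved for FNIP1 WT 991 time course 9709 (from 3002), FNIP1 SA5 991 time course 8393 (from 4399), FNIP1 991 response difference 37 (from 0), all 5 control arms at 4 h 1811 (from 826) and all 5 control arms at 16 h 2571 (from 1076). The lysosomal list and RRAGD turned as above, at the same values.

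Without replicate 1, 2 or 3, which leaves 2 libraries per group, counts ranged over AMPK 991 response difference 1044 to 5150 (from 4376), AMPK CCCP response difference 3652 to 7489 (from 7081), AMPK Phen response difference 318 to 3416 (from 2161), AMPK Rot response difference 18 to 958 (from 488), AMPK DMSO difference 3126 to 5710 (from 5299), FNIP1 WT 991 time course 644 to 7531 (from 3002), FNIP1 SA5 991 time course 1102 to 6982 (from 4399), FNIP1 991 response difference 0 to 6 (from 0) and FNIP1 DMSO difference 46 to 901 (from 1375). They ranged over TFEB and TFE3 991 response difference 747 to 1491 (from 3690), ESRRA 991 response difference 82 to 197 (from 921), ESRRA DMSO difference 1363 to 1849 (from 2870), PGC1A 991 response difference 0 to 8 (from 75), PGC1A DMSO difference 1789 to 2385 (from 3247), all 5 control arms at 4 h 225 to 1184 (from 826) and all 5 control arms at 16 h 267 to 1776 (from 1076). The lysosomal list ranged over AMPK KO minus WT Phen 4 h -0.028 to 0.003, AMPK WT Rot 4 h -0.007 to 0.010, FNIP1 WT 991 4 h 0.176 to 0.210, FNIP1 SA5 minus WT 991 4 h -0.044 to 0.318, TFEB and TFE3 WT 991 4 h 0.113 to 0.139 and ESRRA KO minus WT 991 4 h -0.070 to -0.024. The respiratory chain list ranged over AMPK KO minus WT Rot 16 h -0.048 to -0.007, FNIP1 SA5 minus WT 991 16 h -0.387 to -0.013, TFEB and TFE3 DKO minus WT 991 16 h -0.017 to 0.006 and PGC1A siPGC1A minus siControl 991 16 h 0.020 to 0.064. The cholesterol list ranged over AMPK WT 991 16 h 0.110 to 0.202. The glycolysis list ranged over AMPK KO minus WT 991 16 h -0.032 to 0.030. The PGC-1 list ranged over PGC1A siPGC1A minus siControl 991 16 h -0.085 to -0.048. Among genes, FLCN ranged over AMPK KO 991 4 h -0.116 to 0.094 and FNIP1 WT 991 4 h -0.025 to 0.059, CYCS over AMPK KO minus WT 991 16 h -0.106 to 0.009, RRAGD over FNIP1 SA5 minus WT 991 4 h -0.079 to 0.211, ESRRA over ESRRA KO minus WT 991 16 h -0.227 to 0.241. Fewer libraries leave less power by construction, and which library moved each value was not tested outside the FNIP1 table, where the SA5 minus WT values of RRAGD and the lists without replicate 1 lie close to those with only the first SA5 DMSO library left out.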

Other observations

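The tests on the high FLCN and FNIP1 levels in 3 of the tables were chosen after seeing results. G2/M genes rose in WT cells of the AMPK table at 16 h of 991 (27 of 29 rose, 0 fell and 2 did not pass, the same over the list alone), at a median of 0.49 against 0.07 for all genes (adjusted p = 3.8e-09, and adjusted p = 0.29 with an estimated correlation). HMMR, a mitotic spindle gene, stood at 40.4 ± 0.865 against 20.7 ± 0.324 TPM (0.93 ± 0.07, adjusted p = 1.4e-19). In AMPK KO cells the G2/M response was lower (1 of 29 higher, 20 lower and 8 not passed, or 1 and 25 over the list alone), at a median difference of -0.25 (adjusted p = 6.9e-12, and adjusted p = 0.20 with an estimated correlation), HMMR included (-0.53 ± 0.10, adjusted p = 4.9e-05). Under DMSO these genes were higher in KO (15 of 29 higher, 2 lower and 12 not passed, or 16 and 2 over the list alone; median 0.13, adjusted p = 0.00046, and adjusted p = 0.57 with an estimated correlation). In WT cells of the ESRRA table, G2/M genes rose as well (28 of 29 rose, 0 fell and 1 did not pass, the same over the list alone; median 0.35, adjusted p = 2.8e-13). Those of the FNIP1 table did not pass (2 of 29 rose, 0 fell and 27 did not pass, the same over the list alone; median 0.12, adjusted p = 0.52) but did with quantile normalization (0.151, adjusted p = 0.012).

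Cholesterol synthesis genes were not set apart in WT cells of the AMPK table at 16 h of 991 (11 of 24 rose, 7 fell and 6 did not pass, the same over the list alone; median 0.19, adjusted p = 0.96). Their response was lower in AMPK KO cells (1 of 24 higher, 9 lower and 14 not passed, or 1 and 13 over the list alone; median -0.25, adjusted p = 4.4e-06, and adjusted p = 0.28 with an estimated correlation), with IDI1, an isoprenoid isomerase gene, among the lowest (-1.10 ± 0.21, adjusted p = 0.00013). With phenformin at 4 h the response was also lower in KO (0 of 24 higher, 11 lower and 13 not passed, or 0 and 19 over the list alone; median -0.30, adjusted p = 8.1e-19), INSIG1 (-1.30 ± 0.11, adjusted p = 2.2e-14) and HMGCS1 (-1.06 ± 0.17, adjusted p = 3.4e-05, or adjusted p = 0.10 without replicate 3) among them. CCCP lowered these genes in WT cells at 16 h (1 of 24 rose, 19 fell and 4 did not pass, the same over the list alone; median -0.73, adjusted p = 1.6e-11, and adjusted p = 0.077 with an estimated correlation). Glycolysis genes fell at 16 h of 991 in WT cells of the AMPK table (6 of 22 rose, 13 fell and 3 did not pass, or 8 and 13 over the list alone; median -0.24, adjusted p = 0.00017, and adjusted p = 0.077 with an estimated correlation). The glucose transporter gene SLC2A1 fell to 6.83 ± 0.200 against 16.01 ± 0.266 TPM (-1.12 ± 0.05, adjusted p = 5.1e-33) and the pyruvate kinase gene PKM to 533 ± 1.90 against 798 ± 3.93 TPM (-0.58 ± 0.03, adjusted p = 7.6e-27), while PFKL, a phosphofructokinase gene, rose (0.62 ± 0.11, adjusted p = 2.1e-06). SLC2A1 had the higher response in AMPK KO cells (0.36 ± 0.06, adjusted p = 2.6e-05), but the difference of glycolysis genes as a list did not pass (5 of 22 higher, 1 lower and 16 not passed, or 7 and 2 over the list alone; median 0.00, adjusted p = 0.097), though it did without replicate 3 (0.023, adjusted p = 0.025). In siControl cells the glycolysis list fell too (4 of 22 rose, 13 fell and 5 did not pass, the same over the list alone; median -0.34, adjusted p = 1.1e-11).

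FLCN under DMSO stood at 973, 1012 and 967 TPM in the control arms of the FNIP1, ESRRA and PGC1A tables, against 5.81 and 7.31 TPM in the AMPK and TFEB and TFE3 tables, which were normalized separately, and FNIP1 at 233, 211 and 138 against 2.79 and 4.06 TPM. The levels differed by 34.01 to 174 times and the lengths of the transcripts kept by at most 3.72 times, which argues against a shorter transcript as the whole source. An introduced copy that 991 does not raise would put the 4 h changes of FLCN and FNIP1 below native ones. All 6 lay over 2 standard errors below the AMPK table. The TFEB and TFE3 table (0 of 6 below) cannot decide, as its FLCN (0.03 ± 0.08) and FNIP1 (0.19 ± 0.09) did not pass. The FNIP1 table was fitted without its 2 outlying SA5 libraries, which inflate standard errors (FLCN 0.75, FNIP1 0.73). By design FNIP1 was introduced in the FNIP1 table. Other copies stay open, and changes of both genes in the 3 tables cannot be read as native.

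FNIP1 was higher in siPGC1A than in siControl cells under DMSO (228 ± 5.49 against 138 ± 4.38 TPM; 0.72 ± 0.05, adjusted p = 9.5e-12).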
